A study of Arabidopsis thaliana with 8 samples.

How the data were processed

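Total RNA of mature Arabidopsis leaves was measured on 8 Affymetrix arrays, 2 in each of 4 groups: untreated, clothianidin, imidacloprid and salicylic acid, the last 3 at 4 mM and 4 days before harvest. The deposited values are log2 expression summaries per probe set, made by the authors with RMA and the affy package per the submitters' processing notes, which give no version or order of steps; the background step and any later centring are not stated. The 25th percentile of the arrays averaged 2.49, and values under it were taken as near background. All 8 columns matched a sample label, and none was left out.

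Of 22810 probe sets, 64 control probe sets were left out and 22746 were tested. Genes were named from the probe table of the reference data, joined by gene identifier to the TAIR10.1 annotation: 14016 probe sets had an entry, 503 of them with several genes and 13513 with a single gene, of which 13436 matched a locus and 77 did not. A further 8730 probe sets had no gene in the table, so they count among the calls without a name. The 13436 probe sets covered 13286 loci, and for a locus with several the probe set with the highest mean over all arrays stood for it in tests of gene lists. No coordinates are given, since the files name no genome build.

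The values were fitted in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, all 8 arrays in 1 fit and a mean for each group, which leaves 4 residual degrees of freedom (prior 0.766). The 6 pairwise differences were tested, two-sided, and a probe set was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast. With 2 arrays against 2, an exact permutation test of a single gene cannot reach that threshold, so each call rests on the spread pooled over the groups. Replicates came from independent experiments, but their numbers did not pair the arrays by the rule fixed for it, so the main fit had no block. Replicate differences still correlated at up to 0.523 between groups, so an effect shared by replicate number is not excluded, and a block was an alternative. Confidence intervals are 95% intervals from the same fit.

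The tests, the alternatives, the gene lists and the rule for named genes were set before the data were examined. The rule named 10 genes whatever their values (PR1, PR2, PR5, ICS1, EDS5, PBS3, NPR1, EDS1, PAD4 and WRKY70). It also took the 5 largest rises and 5 largest falls per contrast among called single-locus probe sets whose groups did not overlap, and the top members of a list with at least 3 called members. Where a contrast had no call, it took the 3 smallest p in each direction. None of the 10 genes had a single-gene entry in the probe table, so they were not analysed here. No list had 3 called members.

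Of 502 loci in 29 lists, 78 were measured; 9 members were dropped because the table gave the locus a different symbol. The 11 lists with 3 or more measured members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation. A mean change with its interval was computed for each list from the 8 array means, and members were also adjusted over the list alone. After the data were seen, 21 families of at least 10 loci were formed by gene symbol, without regard to values, and tested the same way; plastid-encoded genes are 1 of them.

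The fit was tested on simulated data with the spread of these arrays. Of 50 probe sets each given a log2 change of 1, 2, 4 and 6, it called 19, 25, 36 and 43, and it called 8 of 22546 without a change. Correlations between contrasts that share the untreated arrays were set beside 100 simulations without any effect. The alternatives were an intensity trend with a robust prior, a fit of only the arrays compared, a replicate block, a filter on dim probe sets, centring on medians, a repeated quantile normalization, a 2-fold threshold, another choice of probe set per gene, an estimated correlation and leaving out each array. Array weights, and leaving out both arrays with the highest actin 3′ minus 5′ difference, were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.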

Results

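Genome-wide transcript levels were measured on Affymetrix arrays in fully expanded leaves of wild-type Arabidopsis thaliana (Columbia-0). The plants were 4 weeks old when they received 4 mM clothianidin, 4 mM imidacloprid or 4 mM salicylic acid, and leaves were collected 4 days later with leaves of untreated plants. Clothianidin and imidacloprid are neonicotinoid insecticides, and salicylic acid is the plant hormone that controls defence against biotrophic pathogens. Each of the 4 groups held 2 arrays, from plants of independent experiments. The stated aim was to record the response to the insecticides. Array means of the log2 values lay between 5.23 (salicylic acid replicate 1) and 5.27 (clothianidin replicate 2), and single values between 1.69 and 15.49.

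Replicate arrays correlated across probe sets, which are not independent replicates, at r = 0.955 in untreated leaves, 0.963 with clothianidin, 0.969 with imidacloprid and 0.919 with salicylic acid. The salicylic acid pair stood furthest apart: the SD of its replicate differences was 1.14 on the log2 scale, against 0.85, 0.76 and 0.70 in the untreated, clothianidin and imidacloprid pairs. Each untreated, clothianidin and salicylic acid array correlated more closely with an array of another group than with its own replicate, up to r = 0.978 between untreated replicate 2 and clothianidin replicate 2, and the imidacloprid arrays did not. The actin 3′ minus 5′ control difference, which rises as RNA degrades, was 0.85 and 2.17 on untreated replicates 1 and 2, 1.04 and 1.75 with clothianidin, 0.87 and 1.11 with imidacloprid, and 0.74 and 1.41 with salicylic acid. It was higher on replicate 2 in every group. The number of arrays limits the precision of every value.

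Imidacloprid gave more calls against untreated leaves than either other treatment. In limma's test 71 of 22746 probe sets differed at an adjusted p under 0.05, 46 of them higher and 25 lower, and 42 of the 71 were named by a single locus. AT2G37130, a class III peroxidase, rose by 6.06 on the log2 scale (SE 0.48), from 2.18 ± 0.19 in untreated leaves to 8.24 ± 0.09 (SD, n = 2; limma adjusted p = 0.0375). The neighbouring genes BGLU45 and BGLU46, which encode beta-glucosidases acting on lignin precursor glucosides, rose by 5.26 (SE 0.36) and 3.80 (SE 0.24). AT1G76470 rose by 4.65 (SE 0.35) and AT5G49690 by 4.34 (SE 0.27). The smallest limma adjusted p, 0.000390, belonged to AT2G35730, at 2.26 ± 0.02 in untreated and 6.30 ± 0.04 in imidacloprid leaves (SD, n = 2).

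Among the other named rises were UGT76E1, a glycosyltransferase gene, at 2.66 (SE 0.10), and SFP1, a gene of the sugar transporter family, at 2.19 (SE 0.19). Among called probe sets named by a single locus, the largest falls after imidacloprid were AT4G23670 at -3.33 (SE 0.26), AT3G10080 at -3.31 (SE 0.30), AT2G39850 at -3.17 (SE 0.26), the signalling peptide gene CLE26 at -2.79 (SE 0.21) and AT2G17650 at -2.63 (SE 0.23). AT4G23670 lay at 13.36 ± 0.03 in untreated leaves and 10.02 ± 0.26 after imidacloprid (SD, n = 2). TBL36, of the cell wall acetylation family, fell by 2.56 (SE 0.20), and psaJ, a plastid gene for a photosystem I subunit, by 1.24 (SE 0.11); both were chosen after their values were seen, as were UGT76E1, SFP1 and BGLU46 in this comparison. Across the 42 named genes the changes ran from -3.33 to 6.06. At 15 of the 71 probe sets the lower group averaged under 2.49, the mean 25th percentile of the arrays, where signal nears background. AT2G37130, AT1G76470, AT5G49690 and AT2G35730 were among these 15, so the sizes and order of their rises are not exact.

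**Figure D1:**
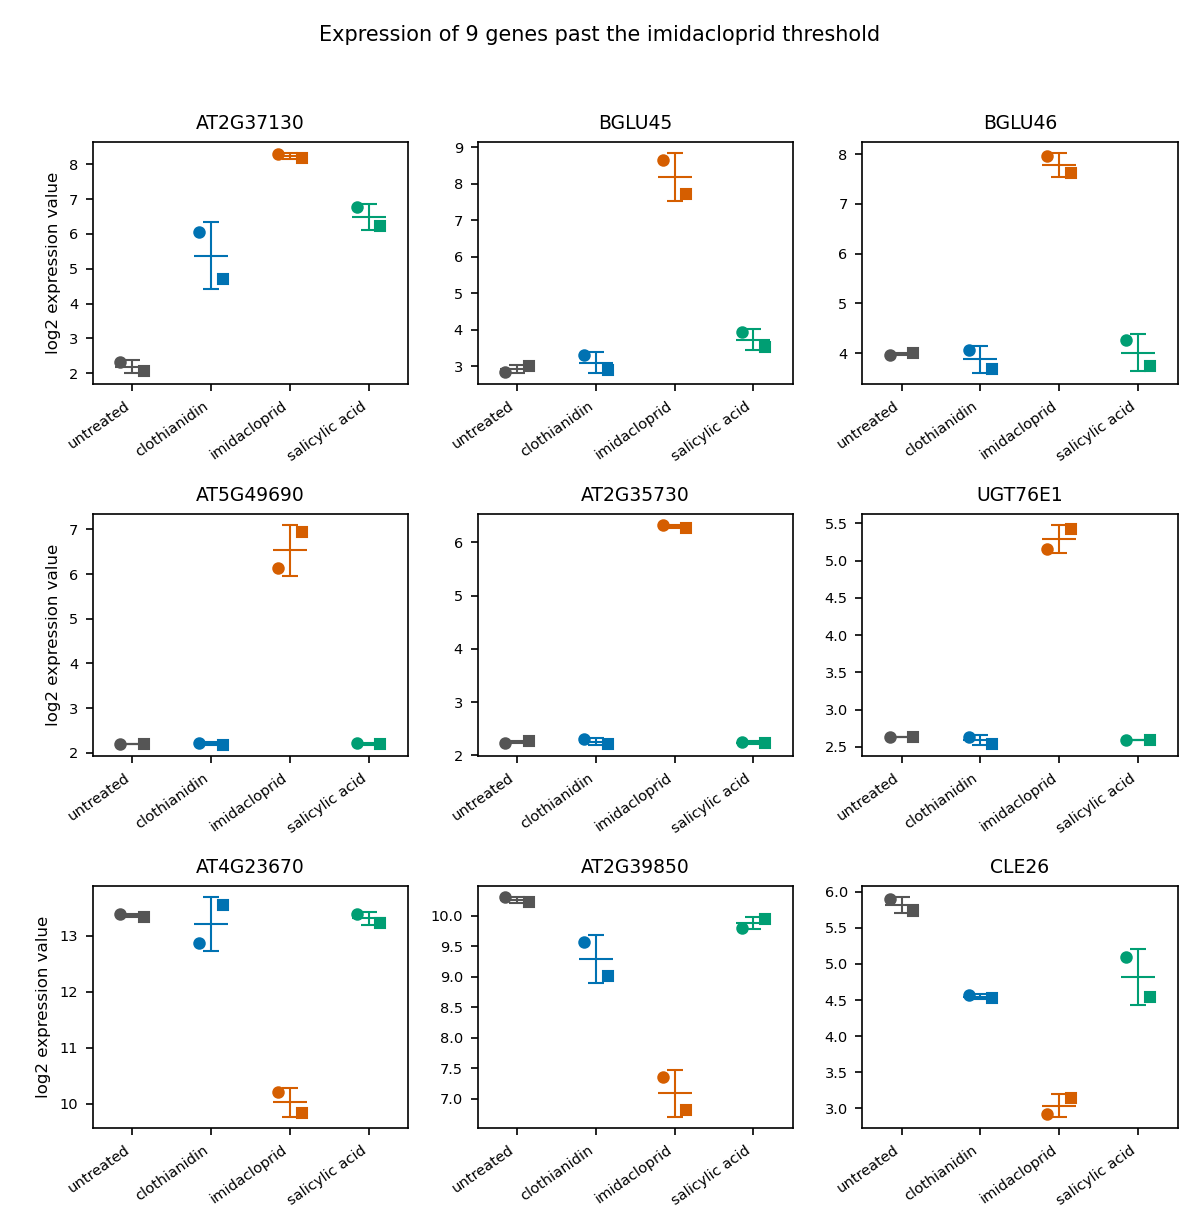
Log2 expression value (vertical axis) of 9 genes past the imidacloprid threshold on each of the 8 arrays, by treatment; circles are replicate 1, squares replicate 2, the dash the mean and the bars 1 SD (n = 2). AT2G35730 lay at 6.30 ± 0.04 with imidacloprid and at 2.26 ± 0.02 in untreated leaves, and AT2G37130 was also above its untreated mean of 2.18 on both clothianidin and both salicylic acid arrays.

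Of the 11 gene lists with enough measured members, 6 passed limma's camera test after imidacloprid, 4 upward and 2 downward. Each list here and below stands only for its measured genes. The 4 upward lists were xenobiotic glycosyltransferase, antioxidant, endoplasmic reticulum and salicylic acid signalling genes. Measured were 8 of 14 xenobiotic glycosyltransferase, 3 of 22 antioxidant and 4 of 16 endoplasmic reticulum genes. Senescence genes, a list that did not pass here, numbered 3 of 17. Abscisic acid, photosynthesis and flavonoid genes numbered 4 of 33, 10 of 53 and 3 of 21. UDP-glycosyltransferases that respond to xenobiotics rose by a mean of 2.43 over 8 members (95% confidence interval 1.39 to 3.48; camera adjusted p = 0.00753), and 6 of the 8 were higher when adjusted over the list alone. UGT73B5 differed by 4.90, UGT73B4 by 4.60, UGT87A2 by 3.71 and UGT73C1 by 3.26. Antioxidant genes rose by 2.38 (0.73 to 4.03; adjusted p = 0.0167), with all 3 members higher when adjusted over the list alone: AT2G21640 by 2.44, the monodehydroascorbate reductase gene ATMDAR2 by 2.38 and the glutathione reductase gene GR1 by 2.32. Genes of the endoplasmic reticulum and secretion rose by 1.69 (adjusted p = 0.0275); the stress transcription factor genes BZIP28 and BZIP60 differed by 1.95 and 1.87, and 1 of the 4 members, BZIP28, passed when adjusted over the list alone. No member of these lists passed over all probe sets. With an estimated correlation none of the 3 calls held (adjusted p = 0.432 with an estimated correlation for each).

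The 6 measured of 38 listed salicylic acid synthesis and signalling genes rose with imidacloprid by a mean of 3.61 (0.66 to 6.56; camera adjusted p = 0.0142; adjusted p = 0.432 with an estimated correlation). ICS1, EDS5, PBS3, NPR1, EDS1, PAD4 and WRKY70 were not among these 6. The largest difference was UGT76B1, whose enzyme glycosylates immune regulators including salicylic acid, at 7.94 (SE 0.99; limma adjusted p = 0.0707), and it alone passed when adjusted over the list alone. GRX480 differed by 4.64, WRKY53 by 4.50 and BSMT1, a methyltransferase gene, by 3.92. The senescence list, which shares WRKY53, differed by 3.08 (-0.53 to 6.69) and did not pass (adjusted p = 0.149); within it WRKY6 differed by 4.90. On the untreated arrays GRX480 had an SD of 3.59 and WRKY53 of 2.22.

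Abscisic acid, drought and cold genes fell with imidacloprid (mean log2 change -2.92 over 4 members, -6.08 to 0.23; camera adjusted p = 0.0432; adjusted p = 0.432 with an estimated correlation). The fall lay in the cold-regulated chloroplast protein genes COR15A at -5.52 and COR15B at -5.19, both lower when adjusted over the list alone, while COR47 and LTI30 differed by -0.29 and -0.70. The list passed in 9 of 18 alternatives: it was lost also with the dim filter and with repeated quantile normalization. Expansin and auxin response genes gave no call (adjusted p = 0.818): their mean was 0.47, but their median was -1.77 and the test pointed down. In that list the auxin-conjugating enzyme genes GH3.3 and WES1 differed by 9.20 and 4.85, both higher when adjusted over the list alone, and the other 5 members were negative. Glutathione S-transferases averaged -0.61 (adjusted p = 0.662), jasmonate and ethylene defence genes 0.04 (adjusted p = 0.622) and flavonoid genes 0.06 (adjusted p = 0.903, with the test pointing down).

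Nuclear photosynthesis genes fell as a list with imidacloprid (mean log2 change -1.22; 95% confidence interval -3.06 to 0.62; camera adjusted p = 0.00199; adjusted p = 0.432 with an estimated correlation). Members ranged from -0.38 for RCA, Rubisco activase, to -1.84 for the Calvin cycle gene SBPASE, all 10 of them negative, and none passed when adjusted over the list alone. Plastid-encoded genes, a group of 69 defined after the data were seen, fell by 0.96 (camera adjusted p = 5.9e-23; adjusted p = 0.660 with an estimated correlation), with 66 of 69 negative and 36 lower when adjusted over the family alone. Within replicate number 1, where the actin differences were 0.87 and 0.85, the nuclear and plastid means differed by -1.24 and -1.02; within number 2 they differed by -1.20 and -0.90. Here and below, the preset correlation of 0.01 takes the plastid genes as nearly independent. Their camera p-values therefore do not measure the spread between arrays. Other probe sets matched to the nuclear list on untreated signal, the choice set before, averaged -0.99. That choice picks probe sets high in 1 arm of the difference. Chosen after the result, those matched on the mean of all arrays averaged -0.38, and those matched on the clothianidin and salicylic acid arrays -0.44.

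**Figure D2:**
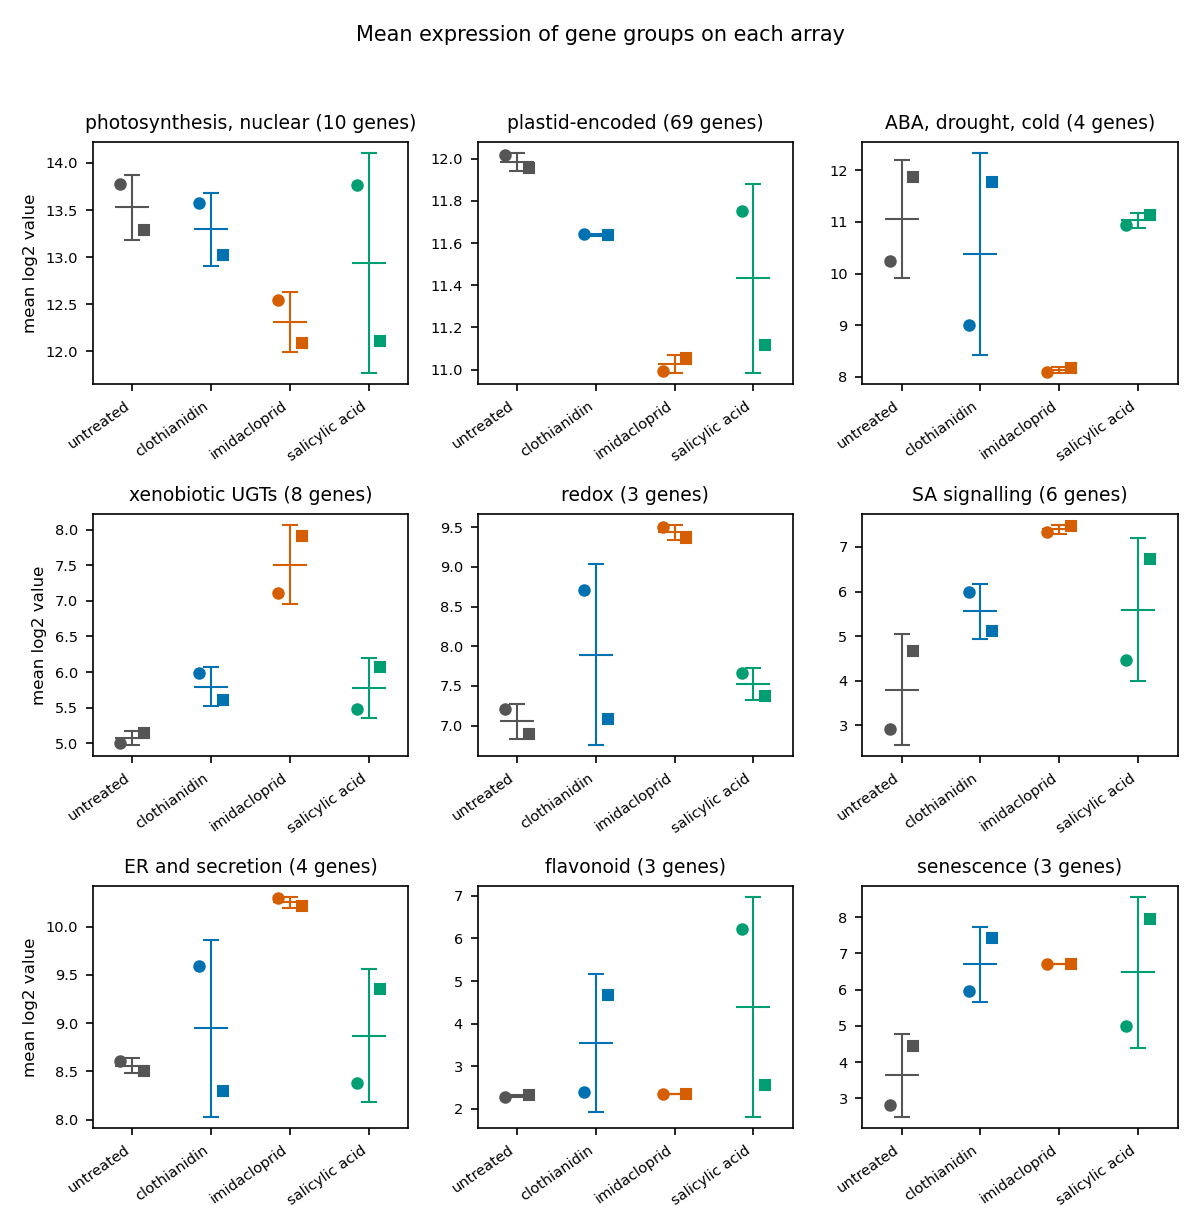
Mean log2 value (vertical axis) of 9 gene groups on each array, by treatment; circles are replicate 1, squares replicate 2, the dash the mean and the bars 1 SD (n = 2). The photosynthesis mean was 12.54 and 12.08 with imidacloprid against 13.78 and 13.29 in untreated leaves, and salicylic acid replicates 1 and 2 lay apart at 13.77 and 12.11.

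The count of 71 was 1 without untreated replicate 1, 173 without untreated replicate 2, 107 without either clothianidin array, 348 and 188 without imidacloprid replicate 1 or 2, and 465 without either salicylic acid array, and it was 0 when untreated replicate 2 and clothianidin replicate 2, the arrays with the highest actin difference, were both left out. Of the 6 lists, 3 passed without untreated replicate 2 and 3 without imidacloprid replicate 1: the antioxidant, endoplasmic reticulum and abscisic acid calls were lost, the second of these also without imidacloprid replicate 2 and the third without either salicylic acid array. At an unadjusted p under 0.05, 4385 probe sets (19.3%, with 5% set by the threshold) differed, 1982 higher and 2403 lower.

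Clothianidin, the other neonicotinoid, gave no probe set past the limma threshold. An unadjusted p under 0.05 was reached by 599 probe sets, 2.63% of those tested, 252 higher and 347 lower, and the trend and robust prior also called 0. The genes with the smallest p, none past the threshold, were AT1G65500 at 4.32 (SE 0.48; limma adjusted p = 0.812), AT4G10270 at 0.58 and AT1G45110 at 0.75 among higher values, and AT3G08630 at -1.25 (SE 0.08; adjusted p = 0.440), AT1G06420 at -0.63 and AT1G65920 at -0.70 among lower ones. AT1G65500 lay at 7.07 ± 0.40 with clothianidin and 2.75 ± 0.61 without (SD, n = 2).

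As groups, 4 lists passed camera upward with clothianidin, but the 95% confidence interval of each list mean included no change. Senescence genes rose by 3.06 (95% confidence interval -0.55 to 6.67; camera adjusted p = 0.00138), with WRKY53 at 4.37, WRKY6 at 2.80 and SAG29 at 2.01. Salicylic acid signalling genes rose by 1.76 (-1.19 to 4.71; adjusted p = 0.00811), with GRX480 at 2.45 and UGT76B1 at 1.05. Antioxidant genes rose by 0.84 (adjusted p = 0.0239) and xenobiotic glycosyltransferases by 0.72 (adjusted p = 0.0497), the latter with UGT73B5 at 2.09 and UGT73B4 at -0.06. No member of any list passed, also when adjusted over the list alone, and all 4 calls were lost (adjusted p = 0.370 with an estimated correlation for each). Salicylic acid signalling genes differed by 3.08 within number 1 and 0.44 within number 2, and antioxidant genes by 1.49 and 0.19. Plastid-encoded genes fell by 0.35 (camera adjusted p = 1.71e-05; adjusted p = 0.849 with an estimated correlation), while nuclear photosynthesis genes averaged -0.24 (adjusted p = 0.677).

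Single arrays decided whether clothianidin gave calls: 72 probe sets passed without untreated replicate 2, and 1 and 2 without clothianidin replicate 1 and replicate 2, while 2 of the 4 lists passed without untreated replicate 2 and 1, senescence, without clothianidin replicate 1, and the senescence call was lost without clothianidin replicate 2. Without clothianidin replicate 1 and replicate 2 the antioxidant mean was 0.03 and 1.65, and without untreated replicate 1 and replicate 2 the signalling mean was 0.88, a lost call, and 2.64. The plastid call was lost without clothianidin replicate 1 (-0.35), and that of the glycosyltransferases without untreated replicate 1 or either imidacloprid array. In data simulated for the imidacloprid comparison with the spread of these arrays, 38%, 50%, 72% and 86% of the 50 probe sets each given a log2 change of 1, 2, 4 and 6 were called.

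Salicylic acid, the hormone treatment beside which the insecticides can be read, also gave no probe set past the limma threshold, with 768 at an unadjusted p under 0.05 and 0 under the trend and robust prior. AT1G65500 had the smallest p among higher genes, at 5.34 (SE 0.48; limma adjusted p = 0.438), followed by REV7 at 0.53 and AT2G37130 at 4.31. AT3G08630 at -1.41, AT1G06420 at -0.63 and AT5G25580 at -0.88 had the smallest p among lower genes (adjusted p = 0.400 for each); none of the 6 passed. Senescence genes rose by 2.85 (95% confidence interval -0.76 to 6.46; camera adjusted p = 0.00688), flavonoid genes rose as a list (adjusted p = 0.0160; members from 1.62 to 2.68), salicylic acid signalling genes rose by 1.80 (-1.15 to 4.75; adjusted p = 0.0160) and xenobiotic glycosyltransferases by 0.70 (-0.34 to 1.75; adjusted p = 0.0160). None of these calls held when the correlation was estimated: adjusted p = 0.336 with an estimated correlation for senescence and glycosyltransferase genes, and 0.459 for the others. The 95% confidence interval of the flavonoid mean, like those of the other called lists, included no change. WRKY53 differed by 4.24, GRX480 by 2.69, UGT76B1 by 2.61 and the anthocyanin gene DFR by 2.68.

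The salicylic acid replicates differed by gene group. Flavonoid genes differed from untreated leaves by 3.95 within replicate number 1 and by 0.25 within number 2, but their untreated means of 2.27 and 2.31 lay under 2.49, near background, so these sizes are not exact. Nuclear photosynthesis genes, at a mean of -0.59 (camera adjusted p = 0.0771), differed by -0.01 and -1.18. Plastid-encoded genes fell by 0.55 (adjusted p = 3.55e-12; adjusted p = 0.682 with an estimated correlation), by 0.27 within number 1 and 0.84 within number 2. Without untreated replicate 2, 82 probe sets passed, and without salicylic acid replicate 1, 37 passed; of the 4 lists 0 passed without untreated replicate 1 and 2 without untreated replicate 2. Without salicylic acid replicate 1 the list means were 0.27 for flavonoid genes, a lost call, 2.93 for signalling and 4.33 for senescence; without replicate 2 they were 3.93, 0.67, a lost call, and 1.37, with 0.41 for glycosyltransferases, and without untreated replicate 1 the signalling mean was 0.92.

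**Figure D3:**
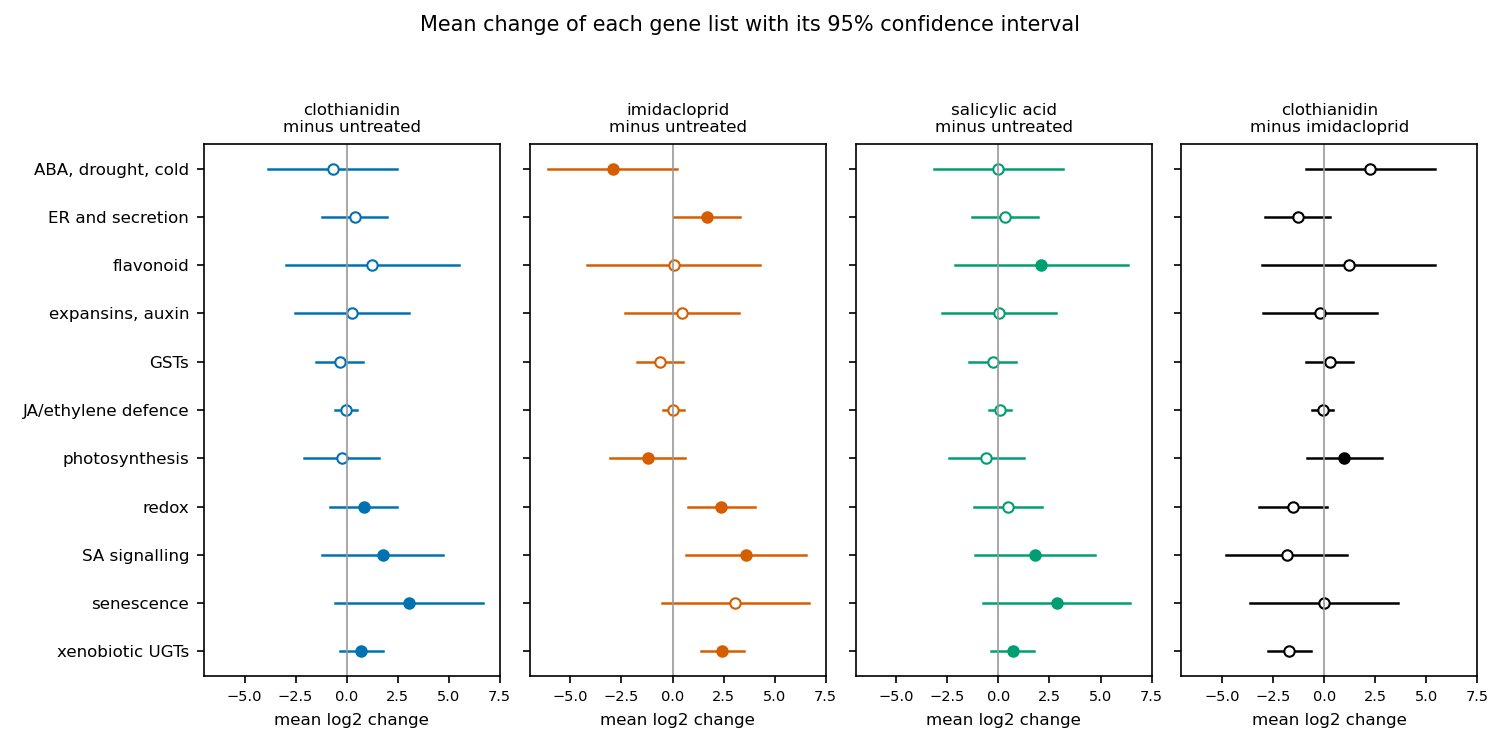
Mean log2 change of each gene list (horizontal axis) in 4 comparisons, with its 95% confidence interval from the 8 arrays; filled points passed the camera test with a preset correlation, open points did not. Xenobiotic glycosyltransferases (UGTs) stood at 2.43 after imidacloprid, 0.72 after clothianidin and 0.70 after salicylic acid; SA, ABA, JA, ER and GST stand for salicylic acid, abscisic acid, jasmonate, endoplasmic reticulum and glutathione S-transferase.

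The 2 neonicotinoids were compared directly at the same dose and time. Both carry a nitroguanidine-type group; clothianidin has an open chain and a chlorothiazole ring, and imidacloprid an imidazolidine ring and a chloropyridine ring. The direct contrast called 22 probe sets in limma's test, 21 lower and 1 higher with clothianidin, and all 22 were among the 71 called for imidacloprid against untreated leaves, a contrast that shares the imidacloprid arrays and the pooled spread. Clothianidin minus imidacloprid, the log2 difference was -5.08 for BGLU45 (95% confidence interval -6.03 to -4.13; limma adjusted p = 0.0494), -4.33 for AT5G49690 (-5.03 to -3.64), -4.04 for AT2G35730 (-4.18 to -3.90), -3.91 for BGLU46 (-4.54 to -3.28) and -3.57 for AT5G57510 (-4.20 to -2.95). With clothianidin AT2G35730 lay at 2.26 ± 0.07 and BGLU46 at 3.88 ± 0.28 (SD, n = 2), beside untreated means of 2.26 and 3.98. At 9 of the 22 the lower group averaged under 2.49, near background. AT5G49690 and AT2G35730 were among these, so their sizes and intervals are not exact. The 46 probe sets raised by imidacloprid had a median change of 2.93 there and of 0.10 with clothianidin. The 25 lowered by imidacloprid had medians of -1.90 and -0.70, and 24 of them were also negative with clothianidin. Both changes were taken against the same untreated arrays. However, a call also asked for a low spread between the clothianidin arrays. The 100 probe sets most raised between the replicate 1 arrays of imidacloprid and untreated leaves, chosen without that, had medians of 5.38 and 1.69 on the replicate 2 arrays.

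Between the insecticides, photosynthesis genes were the 1 list to pass camera with the preset correlation. They were higher with clothianidin by 0.98 (-0.85 to 2.82; camera adjusted p = 0.000903; adjusted p = 0.608 with an estimated correlation). The difference was 1.03 within replicate number 1 and 0.93 within number 2. Plastid-encoded genes were higher by 0.61 (adjusted p = 6.22e-20; adjusted p = 0.841 with an estimated correlation). Xenobiotic glycosyltransferases averaged -1.71 (-2.76 to -0.67; adjusted p = 0.0508), with UGT73B4 at -4.67 and UGT73B5 at -2.81, and 2 of 8 were lower when adjusted over the list alone. For salicylic acid signalling genes the difference was -1.85 (SE 1.06; adjusted p = 0.199), with UGT76B1 at -6.89 and WRKY53 at -0.13. Senescence genes differed by -0.02 (-3.63 to 3.59), flavonoid genes by 1.19 (-3.05 to 5.43) and jasmonate and ethylene defence genes by -0.07 (-0.59 to 0.44); these intervals include 0 and do not show that the compounds act alike. Centring each array on its median shifted all genes in this contrast by -0.16, and in that of imidacloprid minus salicylic acid by 0.14; the photosynthesis, plastid and glycosyltransferase differences kept their sign under it.

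The count of 22 was 1 without either untreated array, 36 and 8 without clothianidin replicate 1 or 2, 279 and 157 without imidacloprid replicate 1 or 2, and 14 without either salicylic acid array. With only the arrays of both insecticides in the fit, or with dim probe sets removed, it was 0. With the replicate number as a block it was 2.

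Each insecticide was also set against salicylic acid. Imidacloprid and salicylic acid differed at 19 probe sets in limma's test, 18 higher and 1 lower with imidacloprid, of which 18 were among the 71 that share the imidacloprid arrays. AT5G49690 was higher by 4.33 (SE 0.27; limma adjusted p = 0.0328), AT2G35730 by 4.06 (SE 0.05), BGLU46 by 3.78 (SE 0.24), AT5G57510 by 3.52 (SE 0.24) and AT3G61930 by 3.46 (SE 0.15). At 9 of the 19 the lower group averaged under 2.49, near background. AT5G49690, AT2G35730 and AT3G61930 were among these, so their sizes are not exact. Abscisic acid, drought and cold genes differed by -2.90 and photosynthesis genes by -0.62, both lower with imidacloprid (camera adjusted p = 0.0169 for both; adjusted p = 0.588 with an estimated correlation). Xenobiotic glycosyltransferases averaged 1.73 higher (0.69 to 2.78) with an adjusted p of 0.0648. The count of 19 was 1 without either untreated array, 276 and 158 without imidacloprid replicate 1 or 2, and 3 with the replicate number as a block.

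Clothianidin and salicylic acid differed at no probe set past the limma threshold, with 277 at an unadjusted p under 0.05 and 0 under the trend and robust prior. Of the genes with the smallest p, none past it, AT1G45110 differed by 1.53 (1.24 to 1.82), AT2G42710 by 0.44, AT2G21290 by 0.44, REV7 by -0.52, the gibberellin receptor gene GID1C by -0.99 (-1.46 to -0.53) and DER2.2 by -0.34. No list passed; the mean difference was -0.04 (-2.99 to 2.91) for salicylic acid signalling and 0.02 (-1.03 to 1.06) for xenobiotic glycosyltransferases. Expansin and auxin, glutathione S-transferase, abscisic acid, senescence and xenobiotic glycosyltransferase lists each had a mean, median or test of differing sign in at least 1 of the 6 contrasts where they did not pass. Calls numbered 19 without salicylic acid replicate 1, and 1 and 2 without clothianidin replicate 1 and replicate 2.

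Across probe sets, which are not independent replicates, the log2 changes of the 3 treatments were positively correlated, at r = 0.742 between clothianidin and imidacloprid, 0.836 between clothianidin and salicylic acid and 0.738 between imidacloprid and salicylic acid, where the shared untreated arrays alone gave 0.501 in simulations without any effect. Their covariances were 0.605, 0.358 and 0.646 against a simulated 0.192, which leaves differences of 0.412, 0.166 and 0.454. A pair of untreated arrays cannot be split with 2 in each part. It was therefore not tested how far the excess correlation comes from these shared controls, or from handling shared by the treatments. Because clothianidin and salicylic acid each gave 0 calls, no calls were shared with imidacloprid and 0 were expected from independent lists. Without untreated replicate 2 the shared calls numbered 71 for clothianidin with imidacloprid, 72 for clothianidin with salicylic acid and 80 for imidacloprid with salicylic acid, but a single untreated array then served all 3 contrasts and the number it gives without any effect was not simulated, so these do not show a shared response; without clothianidin replicate 2 the first was 2, and without salicylic acid replicate 1 the last was 15.

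Markers of other tissues and of harvest time were measured sparsely. The guard cell gene FMA differed by -1.53 with imidacloprid, -0.34 with clothianidin and -0.10 with salicylic acid. The root gene PYK10 differed by -1.50, 0.25 and 1.53, and the clock gene GI by -0.61, -0.29 and -0.11 in the same order. Of commonly used reference genes, AT4G34270 differed by 0.22, 0.37 and 0.11, and PEX4 by -0.41, -0.11 and -0.07. None of these 5 genes passed in any of the 3 comparisons.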

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

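No result met the rules for an outlying sample, opposite effects between groups or a signal outside the main measurement; groups of 2 arrays are too small for the first. Of the tests here, those of RNA quality, of a mislabelled imidacloprid array, of the replicate gap and lists beside a mislabelled untreated array, and of sets matched on all arrays or on the clothianidin and salicylic acid arrays were chosen only after the result was seen.

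Imidacloprid gave 71 calls against untreated leaves in limma's test and clothianidin 0 (599 at an unadjusted p under 0.05). Equal responses hidden by spread were argued against on the 100 probe sets most raised between the replicate 1 arrays of imidacloprid and untreated leaves. On the replicate 2 arrays imidacloprid stood above clothianidin there by a median of 3.72, at 5.38 and 1.69 over untreated. The clothianidin replicates themselves lay a median of 2.30 apart on these probe sets, and the difference compares 1 array with 1 array. Poorer RNA on untreated replicate 2 was argued against for this difference between the insecticides, with the same limit. Probe sets chosen the same way on the replicate 2 arrays differed by a median of 2.85 between the replicate 1 arrays, beside a clothianidin replicate gap of 2.39. For the absence of clothianidin calls, poorer RNA on untreated replicate 2 cannot be told apart from a weak response. Without that array clothianidin gave 72 calls, all against a single untreated array, and without both high-actin arrays clothianidin and imidacloprid each gave 0. A stronger response to imidacloprid than to clothianidin at this dose and time may underlie the difference, as a hypothesis found and tested on the same arrays.

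The salicylic acid replicates stood apart (r = 0.919). An array effect shared with untreated replicate 2 was not excluded as the whole cause. The replicate difference still correlated with the imidacloprid change at r = 0.437 across probe sets once the untreated difference was removed (0.534 before). The untreated difference comes from a single pair of arrays, so its removal may be incomplete. Before removal it correlated at 0.523 with the salicylic acid difference and at 0.354 with the imidacloprid change. Replicate 1 as a mislabelled untreated array cannot be told apart: the 100 probe sets most raised between the replicate 2 arrays differed by a median of 1.101 between the replicate 1 arrays, above the bound of 0.5 set before but within the clothianidin replicate gap of 1.15 on them, and of the 11 lists only the flavonoid mean, 6.22 against 2.27 and 2.31 near background, lay further from untreated than other replicates lay apart. Replicate 2 as a mislabelled imidacloprid array cannot be told apart either: its median position (0 untreated, 1 imidacloprid) was 0.0323 on the 46 higher calls, which ask for a low spread between the salicylic acid arrays, but 0.644 on the 465 calls of a fit without these arrays, with quartiles of 0.388 and 0.874, and in place of imidacloprid replicate 1 or 2 in that fit it left 0 and 3 calls, too few to place the array held out. In other tests tried, the median position on sets chosen on replicate 1 was 0.585. The gap to the held-out imidacloprid array was 2.01 or 4.01 beside clothianidin gaps of 2.30 and 2.39. The imidacloprid replicates lay 1.41 apart on the second of these sets, which was chosen on 1 of them. Of 11 lists, 3 lay beyond the replicate gaps of other groups: abscisic acid (11.14 against 8.18), antioxidant (7.38 against 9.36) and glycosyltransferase genes (6.07 against 7.11). Salicylic acid replicate 2 correlated at 0.943 and 0.930 with the imidacloprid arrays, which correlated at 0.969 with each other. It correlated at 0.969 with clothianidin replicate 2, but other arrays also correlated best outside their group, so this does not settle it. A difference between the independent experiments was not tested.

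Nuclear photosynthesis genes and plastid-encoded genes were lower with imidacloprid. Poorer RNA on untreated replicate 2 was argued against, since the list differed by -1.24 and the plastid genes by -1.02 between the replicate 1 arrays. Compression of bright probe sets by the normalization was argued against for the plastid genes only by the matchings chosen after the result. Of 10000 random sets matched on the mean of all arrays 0% were as low, and 0.01% when matched on the clothianidin and salicylic acid arrays. These sets draw probe sets singly, without the correlation among plastid genes, so such shares overstate the evidence. Matching on untreated signal, set before, gave 22.8% for the plastid genes and 26.6% for the photosynthesis list. It picks probe sets high in 1 arm of the difference and was not used. For the photosynthesis list compression cannot be told apart from a specific fall, since 1.08% and 3.54% were as low under the later matchings, between the bounds of 1% and 5%. A biological fall in photosynthesis transcripts stays open beside it.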

How the results depend on the processing

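Of the tests here, array weights and leaving out both arrays with the highest actin 3′ minus 5′ difference were chosen only after the result was seen. All 20 results of called named genes kept their sign under every one of the 19 alternatives in which they had a value. These genes were chosen for groups that did not overlap, so leaving out an array could not reverse a sign, and the kept signs are no support. Only 163 of their 304 alternative values stayed past the threshold. AT2G35730 passed most often, in 14 of 15 alternatives against untreated leaves, and BGLU45 between the insecticides least often, in 4 of 15. Signal near background limits what can be said of dim genes: 15 of the 71 imidacloprid calls had a group mean under 2.49, and their changes are least exact.

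Calls for imidacloprid against untreated leaves numbered 174 with only these groups in the fit (20 shared with the 71), 576 with the dim filter (27 shared), 189 with median centring (60 shared), 353 with array weights (71 shared) and 0 without both high-actin arrays; with only the 2-fold threshold added they numbered 64. The array weights were equal for both arrays of each group. That setting therefore weighted whole groups and could not mark down a single poor array. The replicate differences of the 6 pairs of groups correlated at 0.302, 0.523, 0.230, 0.361, 0.0549 and -0.00200. The replicate numbers were therefore not taken to pair the arrays. With the replicate number as a block, calls for imidacloprid numbered 43 (23 shared), those between the insecticides 2 and those for imidacloprid minus salicylic acid 3. The trend and robust prior gave 37 calls between the insecticides and 42 for imidacloprid minus salicylic acid; a fit of only the groups compared, the dim filter and leaving out both high-actin arrays each gave 0 in both. The dim filter and the smaller fit change how many probe sets or arrays enter; for the others the cause was not tested.

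Lists past camera for clothianidin numbered 2 with the dim filter and 2 with repeated quantile normalization. For salicylic acid they numbered 1 with only the groups compared, 2 with the dim filter and 2 without both high-actin arrays. Between the insecticides they numbered 2 with only the groups compared, 4 with the dim filter, 3 with median centring, 2 with repeated quantile normalization and 3 with array weights. An estimated correlation gave 0 for clothianidin, imidacloprid, salicylic acid and between the insecticides. The cause was not tested.

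Leaving out 1 array at a time, the lone array of its group being taken to vary like the others, calls ranged from 0 to 72 for clothianidin, 1 to 465 for imidacloprid and 0 to 82 for salicylic acid, each against untreated leaves. They ranged from 1 to 279 between the insecticides, 0 to 19 for clothianidin minus salicylic acid and 1 to 276 for imidacloprid minus salicylic acid. The lowest imidacloprid count, 1, came without untreated replicate 1 and the highest without either salicylic acid array; the 72 and 82 came without untreated replicate 2, the 279 and 276 without imidacloprid replicate 1 and the 19 without salicylic acid replicate 1. Shared calls ranged from 0 to 71 for clothianidin with imidacloprid, 0 to 72 for clothianidin with salicylic acid and 0 to 80 for imidacloprid with salicylic acid, the highest each time without untreated replicate 2, where all contrasts share a single untreated array. Lists past camera ranged from 1 to 5 for clothianidin, 3 to 6 for imidacloprid, 0 to 5 for salicylic acid and 1 to 4 between the insecticides. The lowest of these came without clothianidin replicate 1 (1), without untreated replicate 2 or imidacloprid replicate 1 (3) and without untreated replicate 1 (0), and the 4 without clothianidin replicate 1. The cause was not tested.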

Other observations

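The families formed by gene symbol, and the single genes named here, were chosen only after the data were seen; no explanation is tested in this part. IQD genes, whose proteins bind calmodulin, fell with imidacloprid by 1.18 over 15 members (camera adjusted p = 0.00809; adjusted p = 0.660 with an estimated correlation), and 3 were lower when adjusted over the family alone: IQD30 at -2.97, IQD28 at -2.87 and IQD24 at -2.36. The whole UDP-glycosyltransferase family averaged 1.01 over 47 members with imidacloprid (adjusted p = 0.104), with 10 higher and 2 lower when adjusted over the family alone. UGT76E12 differed by 6.44, UGT73C7 by 4.94, UGT78D1 by -2.53 and UGT88A1 by -1.25. Among 29 serine carboxypeptidase-like genes (adjusted p = 0.125), 4 were lower when adjusted over the family alone, scpl50 at -2.79 the furthest. Among 15 endoglucanase genes of family GH9 (adjusted p = 0.456), GH9B7 differed by -4.50 and GH9B8 by -1.27.

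Lists with too few measured members for a test held large differences that did not pass over all probe sets. The chitinase gene CHI differed by 8.42 with imidacloprid, 6.58 with clothianidin and 6.30 with salicylic acid. In the same order the immune kinase gene BIK1 differed by 2.69, 1.22 and 1.49, the alkenal reductase gene AER by 2.83, 1.08 and 0.50, and the heat shock gene ATHSP22.0 by 4.30, 2.79 and 0.45. BCAT4, of methionine chain elongation for glucosinolates, differed by -3.34, -0.26 and 0.24, and PORB, of chlorophyll synthesis, by -2.64, -0.56 and -1.03.

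Among the control probe sets, the 5′ ubiquitin control stood at 13.16 ± 0.26 (SD, n = 2) in untreated leaves and above both of these arrays with every treatment, at 14.34 ± 0.10 with imidacloprid, 13.75 ± 0.04 with clothianidin and 13.91 ± 0.40 with salicylic acid. In the same order the 3′ ubiquitin control stood at 12.93 ± 0.13, 13.74 ± 0.04, 13.30 ± 0.16 and 13.50 ± 0.49.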
